A study of Mus musculus with 6 samples.

How the data were processed

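Gene expression was measured on Affymetrix whole-genome mouse arrays, which read the 3′ part of transcripts with groups of short probes called probe sets. The RNA was total RNA from neonatal mouse tail tip fibroblasts, extracted with a Qiagen RNeasy kit and labelled with biotin by the GeneChip 3′ IVT Express chemistry, per the labels' protocols. There were 6 samples, 3 wild type and 3 *Hotair* knockout, each on its own array, from mice backcrossed to C57BL6. The deposited values are log2 probe set summaries made by RMA in R 2.11.1, per the submitters' processing notes. RMA corrects background, equalises the distribution of probe intensities across arrays and summarises the probes of a set, so a change in total RNA content cannot be seen and differences of dim probe sets are compressed. The annotation package used upstream was not given in the sources used here.

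Probe sets were named from a platform annotation table. Of 45101 probe sets, 64 were controls, 34945 of the other 45037 had 1 gene, 932 had several and 9160 had none. No gene was named from a probe set with several. Of the probe sets with 1 gene, 99.42% matched the gene table of assembly GRCm38.p6 by their Entrez identifier. This table changed 0 symbols and was used only for names and for the order of genes. Each of 18193 genes was represented by its single-gene probe set with the highest mean over the 6 arrays. *Hotair* was not analysed here, because 0 probe sets were named for it, so the genotype labels were not checked against their target. *Hoxc11*, *Hoxc12* and *H19* were not analysed here, as no probe set was named for them alone.

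Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on the log2 scale, with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. A second fit took all 45037 probe sets. Lists of genes were written before the data were examined and tested with camera (preset correlation 0.01, two-sided, adjusted over the 34 sets tested), again with an estimated correlation, and with fry. A list needed at least 4 measured genes, which left out the Y-linked list. The 100 measured genes on each side of the Hoxc cluster, or as many as the chromosome held, were tested in the same way. The labels do not say whether samples of a genotype came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision: an exact permutation test of a single value between 3 and 3 arrays cannot go below 0.1.

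The genotypes share replicate numbers in the labels. Deviations from the genotype means correlated at 0.50, 0.49 and 0.25 between arrays numbered 1, 2 and 3. By the rule fixed beforehand the numbers were therefore taken to pair the arrays. Wild-type array 3, however, correlated best with knockout array 2 (0.33). Deviations cancel within a genotype, so a replicate 1 that stands apart in both genotypes makes arrays 2 and 3 correlate across genotypes by itself. The correlations therefore do not show that the numbers 2 and 3 pair arrays, and results by block or replicate number depend on this. With the replicate number as a block, limma called 0 genes and 0 probe sets.

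Genes were named by a rule. *Hotair*, the Hoxc genes, *Hoxd10* to *Hoxd13*, *Dlk1*, *Meg3*, *H19*, *Igf2*, *Peg3*, *Mest*, *Ezh2*, *Suz12* and *Kdm1a* were named where measured. The rule then took, in each direction, the 12 largest changes among genes that passed and whose knockout values all lay on one side of the wild-type values, passing over predicted models and clone names. As no gene passed over all 6 arrays, its fallback applied: the 6 with the smallest p in each direction were added as values, with the member of smallest p in each list and the sex-linked checks. Some genes were named after their values were seen, and these are marked where they appear. Alternatives were the block, other eBayes priors, a filter on dim genes, renormalisation, array weights, leaving out each array, other choices of probe set, other thresholds, an ordinary equal-variance test per gene and a Y-linked covariate. Leaving out both arrays of replicate 1, and a batch term for them, were added after seeing the data.

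The scripts were tested on simulated data with the means and spreads of the 18193 genes, in which 50 genes were changed at each of 4 sizes. Without the block, the share recovered was 24% at a true log2 change of 1, 56% at 2, 82% at 3 and 84% at 4. With the replicate block the shares were 0%, 36%, 64% and 80%. False calls numbered 12 without and 1 with the block. A simulated list of 20 genes shifted by 0.5 was called by camera (adjusted p = 1.04e-07), and 0 of 33 unshifted lists were. The simulated genes varied independently of each other, so this does not show how often camera falsely calls lists of correlated genes.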

Results

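The arrays compared cultured fibroblasts from the tail tips of newborn mice that were wild type or lacked *Hotair*, a long noncoding RNA transcribed from the Hoxc cluster of developmental patterning genes. The title of the series names homeotic transformation and imprinted genes, so the questions were which genes differed between genotypes and whether Hox and imprinted genes were among them. There were 3 arrays per genotype, and the medians of the log2 values lay between 5.57 and 5.68 on the 6 arrays. *Hotair* itself was not analysed here.

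The arrays did not separate by genotype alone. The first principal component, with 48.9% of the variance, set replicate 1 of both genotypes (−114.7 and −82.7) apart from the 4 other arrays (39.3 to 74.7). Genes of cell proliferation were low on these arrays, with list medians of −2.0 in wild type and −1.38 in knockout against 0.54 to 1.17 on the others, relative to each gene's mean. The second component, with 29.9%, set wild-type replicates 2 and 3 (75.3 and 66.0) apart from knockout replicates 2 and 3 (−59.1 and −71.0), with replicate 1 of both between them. Pearson's r over all probe sets, which are not independent replicates, was 0.984 between the replicate 1 arrays, 0.985 between wild-type replicates 2 and 3 and 0.983 between knockout replicates 2 and 3, and 0.930 to 0.963 for other pairs. The 3′ minus 5′ difference of the control probe sets, a sign of RNA degradation, was 0.63 for *Actb* and 0.75 for *Gapdh* in knockout replicate 1, against at most 0.21 and −0.03 on the other arrays. *Xist*, the RNA of the inactive X chromosome, was low everywhere (5.37 ± 0.20 in wild type and 5.11 ± 0.06 in knockout, SD, n = 3), and the Y-linked *Eif2s3y* measured 7.64, 4.28 and 7.41 in wild type and 8.33, 10.34 and 10.39 in knockout. Of the other Y-linked genes, *Kdm5d* was 7.41 ± 0.04 in wild type and 8.01 ± 0.12 in knockout, and *Uty* differed by 0.39 ± 0.85 (SE). The Y-linked list of 3 genes had 2 members higher in knockout when adjusted over the list alone, *Eif2s3y* and *Kdm5d*. The other probe set of *Eif2s3y* differed by only 0.03, and 2 of 3 probe sets of *Kdm5d* were higher, with its lowest at −0.10.

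**Figure D1:**
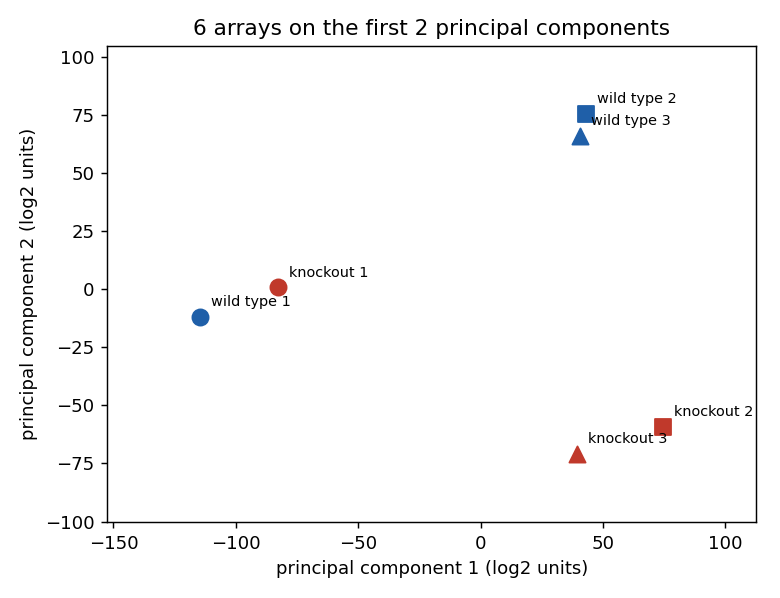
Each point is 1 of the 6 arrays on the first and second principal components of the log2 values, blue for wild type and red for knockout, with the replicate number beside it. Replicate 1 of both genotypes lies at −114.7 and −82.7 on component 1, and the genotypes part on component 2 in replicates 2 and 3.

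No gene passed the test between genotypes over all 6 arrays. The genes with the smallest p that were higher in knockout included *Fzd1*, a Wnt receptor (10.14 ± 0.10 in wild type, 11.29 ± 0.17 in knockout, SD, n = 3), and *Lgr4*, a receptor for R-spondins (a difference of 1.56 ± 0.21, SE). *Csrnp2*, *Flrt1*, *Gramd1c* and *Hivep3* were higher by 0.93, 1.11, 0.79 and 1.94. On the lower side stood *Ankrd1*, a target of the Hippo pathway (10.93 ± 0.23 in wild type and 7.36 ± 0.85 in knockout, SD, n = 3), and *Flt1*, a VEGF receptor, at −1.54 ± 0.26 (SE), and *Pdlim1*, *Klf6*, *Fgf2* and *Ppp2cb* were at −0.81, −1.27, −1.32 and −0.80. Some of their probe sets disagreed: 1 of 2 for *Lgr4* and 1 of 3 for *Pdlim1* went the other way, at −0.10 and 0.13. By limma, 0 of 18193 genes had an adjusted p under 0.05 (smallest 0.743). At an unadjusted p under 0.05 there were 1216 genes, 730 higher and 486 lower, against 910 expected by chance, and the ordinary equal-variance test gave 895 and likewise 0 after adjustment. There were 2017 with the replicate block, 1248 higher and 769 lower, and again 0 after adjustment (smallest 0.424). The 3 knockout values all lay on one side of the wild-type values for 1807 genes, 9.93% against the 10% that chance gives without pairing. Within pairs, 30.5% of genes differed in the same direction in all 3, and 20%, 13.6% and 35.5% did when the labels of 1 pair were swapped. Over all 45037 probe sets limma called 0, with 2406 at unadjusted p under 0.05 and 4001 with the block. Array weights, however, called 2101 genes but 0 probe sets (smallest adjusted p 0.0927), and leaving out knockout replicate 1 called 87 genes and 48 probe sets. Without replicate 1 of both genotypes, an alternative added after seeing the data, limma called 2542 genes, 1375 higher and 1167 lower, and 1836 probe sets.

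No Hox gene passed the test between genotypes. In the cluster that holds *Hotair*, *Hoxc4* differed by 0.53 ± 0.35 (SE), *Hoxc5* by −0.36 ± 0.18, *Hoxc6* by 0.17 ± 0.16, *Hoxc8* by −0.02 ± 0.97, *Hoxc9* by 0.07 ± 0.23, *Hoxc10* by −0.03 ± 0.25 and *Hoxc13* by −0.41 ± 0.39. The distal genes of the Hoxd cluster were dim, with wild-type means of 3.67 for *Hoxd10*, 4.66 for *Hoxd11*, 4.06 for *Hoxd12* and 4.86 for *Hoxd13*, and differences of 0.26, −0.02, −0.02 and 0.09. Of the 33 measured Hox genes 0 passed, also when adjusted over the list alone, and their median difference was −0.03 (camera adjusted p = 0.244). The medians were −0.17 for 9 HoxA genes (adjusted p = 0.385), −0.26 for 9 HoxB genes (0.357), −0.02 for 7 HoxC genes (0.963), −0.02 for 8 HoxD genes (0.713) and −0.01 for 14 posterior Hox genes (0.963). Leaving out 1 array moved them to between −0.153 and −0.044 for all Hox genes, −0.21 and −0.058 for HoxA and −0.57 and −0.067 for HoxB, and called none (smallest adjusted p 0.0843). Members with the smallest p were *Hoxa7* (−0.44), *Hoxb13* (0.48) and *Hoxd8* (−0.55). Among 47 other transcription factors of body position the median was 0.07 (adjusted p = 0.963), with *Msx2*, a limb and skin factor, at −2.47 ± 0.71 (SE). With array weights the list of all Hox genes was called lower (median −0.16, adjusted p = 0.031).

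The RNAs of the imprinted Dlk1-Dio3 region were higher in knockout. *Dlk1*, a paternally expressed Notch-like protein, was 6.65 ± 0.24 in wild type and 8.83 ± 1.28 in knockout (SD, n = 3), and the maternally expressed noncoding RNA *Meg3* was 10.51 ± 0.48 and 12.41 ± 1.06. *Rian* and *Mirg*, named after their values were seen, differed by 2.23 ± 0.78 and 1.93 ± 0.63 (SE). All 4 measured members rose when adjusted over the list alone and 0 did over all genes, and their median was 2.05 (camera adjusted p = 0.000168; adjusted p = 0.814 with an estimated correlation). The preset correlation of 0.01 takes the 4 RNAs as nearly independent, although they lie in 1 region. The title of the series names imprinted genes, so the direction of the rise is not independent of the study. By replicate number the median differences were 0.64, 3.56 and 1.89, and *Rian* was −0.23 within replicate 1. *Dlk1* rested most on knockout replicate 1 (10.29, against 7.91 and 8.28), the array with the sign of RNA degradation, and differed by 1.44 without it. A second probe set of *Dlk1* differed by −0.01, while 11 of 11 probe sets of *Meg3* were higher.

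**Figure D2:**
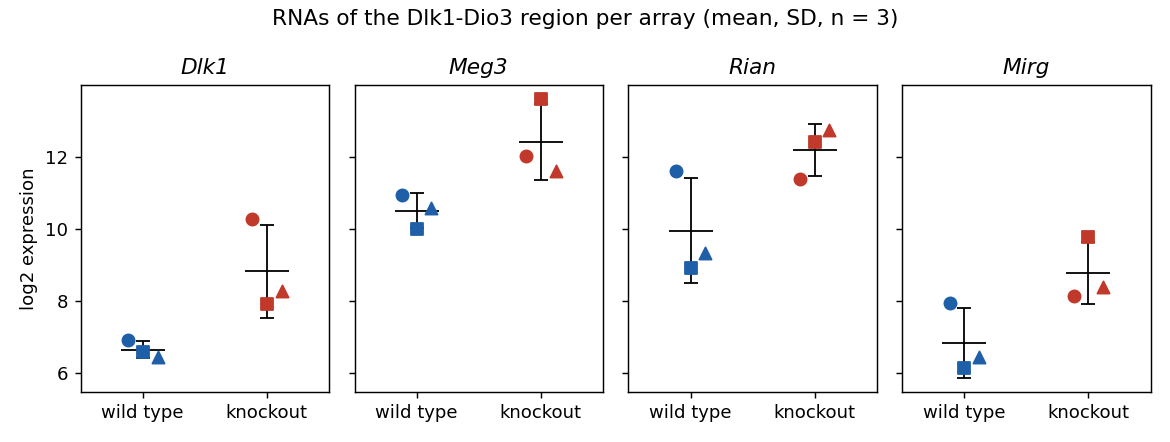
The log2 expression of 4 RNAs of the Dlk1-Dio3 region is shown per array, with circles, squares and triangles for replicates 1, 2 and 3, and with the mean and SD of 3 arrays. The mean of *Meg3* is 10.51 in wild type and 12.41 in knockout.

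No shift was called for imprinted genes as a whole. Of 67 measured, 39 lay above 0 and 28 below, with a median of 0.02 (camera adjusted p = 0.385), and 0 passed when adjusted over the list alone. The 27 paternally expressed genes had a median of 0.02 (adjusted p = 0.381) and the 40 maternally expressed genes one of 0.03 (adjusted p = 0.704). With the replicate block, however, 2 of all imprinted genes rose when adjusted over the list alone, *Slc38a4* and *Plagl1*, a zinc finger factor (2.35), and 3 of the paternally expressed genes did, these and *Dlk1*. *Slc38a4*, an amino acid transporter, was at 1.68 ± 0.32 (SE), *Igf2r*, the receptor that clears insulin-like growth factor 2, at 1.20 ± 0.35 and *Mest* at 1.45 ± 0.61. *Igf2* (0.41 ± 0.69) and *Peg3* (−0.00 ± 0.58) differed by less than their errors without the block. With it the error of *Igf2* was 0.34, below its difference, but by replicate number it differed by 1.28, −0.32 and 0.25. The cell cycle inhibitor *Cdkn1c* was at 1.46 ± 0.53, and it and *Plagl1* were named after their values were seen.

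No shift was called for the chromatin regulators linked to *Hotair* in earlier work. *Ezh2* and *Suz12*, core subunits of Polycomb repressive complex 2, differed by 0.41 ± 0.78 and 0.21 ± 0.71 (SE), and the demethylase *Kdm1a* by −0.27 ± 0.28. By replicate number *Ezh2* differed by 0.48, 0.23 and 0.50, and *Suz12* by 1.03, 0.22 and −0.61. With the replicate block the SE of *Ezh2* was 0.15, and it did not pass (limma adjusted p = 0.449). The medians of the complex 2 list by replicate number were 0.48, 0.073 and 0.19. The median was 0.13 for 13 subunits of this complex, where the mean was 0.00 and the test pointed down (camera adjusted p = 0.963), with *Rbbp4* at 0.31. Without wild-type replicate 1, however, this list was called lower (median −0.27, adjusted p = 0.0183), while without wild-type replicate 2 or 3 or knockout replicate 1 its test pointed up (0.30, 0.165 and 0.37). The median was 0.12 for 18 subunits of complex 1 (adjusted p = 0.688; *Cbx6* at 0.68) and 0.05 for 13 genes of the LSD1, CoREST and REST complex (adjusted p = 0.963; *Hdac1* at 0.41).

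Stress and growth programmes shifted between genotypes by camera with its preset correlation. A list of targets of the tumour suppressor p53 and senescence genes, called p53 targets or the p53 list here, was lower in knockout. Its median was −1.07 over 15 genes of which 14 lay below 0 (adjusted p = 7.9e-06), and *Bbc3*, which promotes cell death, stood at −0.64 ± 0.20 (SE). With an estimated correlation the adjusted p of this list was 0.969, and its median was −1.77 without knockout replicate 1 and −0.70 without knockout replicate 3. With the replicate block 1 member, *Phlda3* (−1.37), named after its values were seen, fell when adjusted over the list alone. Immediate early genes, the first to answer growth signals, had a median of −0.83 over 21 genes (adjusted p = 7.9e-06; adjusted p = 0.969 with an estimated correlation), and *Klf6* fell when adjusted over the list alone. Hypoxia and glycolysis genes had a median of −0.56 over 21 genes (adjusted p = 0.000168, and 0.969 with an estimated correlation), with *Pgam1* at −0.56. Cholesterol synthesis genes were higher, with a median of 0.56 over 17 genes (adjusted p = 0.00303, and 0.969 with an estimated correlation), and *Hsd17b7* stood at 1.05 ± 0.34 (SE). By fry 0 lists were called, and 0 members passed over all genes. By replicate number the medians were 0.00, −1.66 and −1.38 for p53 targets, −0.03, −0.60 and −1.93 for immediate early genes, −0.04, −0.46 and −1.18 for hypoxia genes, and −0.33, 0.84 and 1.11 for cholesterol genes. A difference of replicate 1 from replicates 2 and 3, a grouping chosen after seeing the data, had adjusted p of 4.07e-06, 0.000346, 0.00227 and 3.74e-07 by camera, but 0.718, 0.88, 0.88 and 0.718 with an estimated correlation, and replicate 1 has 1 array per genotype. The same test also called leukocyte markers (0.00239, and 0.718 with an estimated correlation) and the genes beside the Hoxc cluster (0.00227, and 0.88). Leaving out wild-type replicate 3 ended the call of the hypoxia list (median −0.24, adjusted p = 0.316). The call of the cholesterol list ended without wild-type replicate 1 (0.48), knockout replicate 2 (0.24) or knockout replicate 3 (0.24), and its median was 0.98 without knockout replicate 1.

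**Figure D3:**
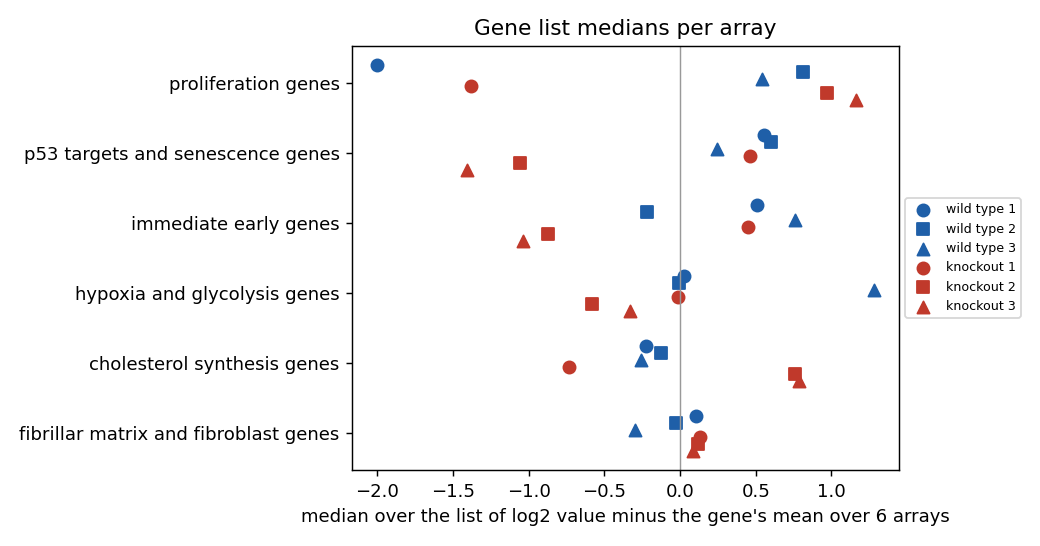
Each point is the median over a gene list, on 1 array, of the log2 value minus the gene's mean over the 6 arrays. The p53 list lies at −1.06 and −1.41 in knockout replicates 2 and 3 and between 0.25 and 0.60 on the 4 other arrays.

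Calls of growth and matrix genes depended on the pairing and choice of arrays. The median was 0.48 for 31 proliferation genes, of which 28 lay above 0 (camera adjusted p = 0.146, and 8.57e-07 with the replicate block, or 0.937 with the block and an estimated correlation), with *Ccne1* at 0.53. It was 0.24 for 24 fibrillar matrix and fibroblast genes (adjusted p = 0.0600, and 0.0457 with the block or 0.937 with an estimated correlation too), where *Dcn*, a matrix proteoglycan, was 9.27 ± 2.13 in wild type and 12.37 ± 0.74 in knockout (SD, n = 3), a difference of 3.10 that was 1.9 without wild-type replicate 2. The other probe set of *Dcn* was at 0.53. The 14 smooth muscle and myofibroblast markers had a median of −0.15 (adjusted p = 0.0946, and likewise 0.0457 and 0.937), with *Ccn2* at −2.79 ± 0.94 (SE). With the replicate block 3 matrix genes rose when adjusted over the list alone, *Lum* (2.64), *Pdgfra* (1.65) and *Ddr2* (0.96), named after their values were seen. Without wild-type replicate 1 *Pdgfra* was at 0.965 and *Ddr2* at 0.295, and without knockout replicate 1 they were at 2.5 and 1.49. By replicate number the medians were 0.53, 0.33 and 0.51 for proliferation genes, 0.15, 0.066 and 0.41 for matrix genes and −0.45, −0.28 and 0.16 for smooth muscle markers. The fits that leave out 1 array had no block, so they also leave its partner unpaired. Without wild-type replicate 2, wild-type replicate 3 or knockout replicate 1 the proliferation list was called higher (0.91, 0.815 and 1.23). Without wild-type replicate 1, however, it pointed down (−0.52, adjusted p = 0.121), and without knockout replicate 2 or 3 its median was 0.048 and −0.054. The matrix list was called without wild-type replicate 2 (0.34) or knockout replicate 3 (0.32), while without wild-type replicate 3 its median was 0.082 (adjusted p = 0.235). The smooth muscle list was called without wild-type replicate 3 (−0.34) or knockout replicate 1 (−0.29), but without wild-type replicate 1 it pointed up (0.067, adjusted p = 0.649).

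Over all 6 arrays no shift was called for the markers of other cell types. The medians were −0.03 for 20 skeletal muscle markers (camera adjusted p = 0.722; *Acta1* at −2.27), 0.02 for 16 cartilage markers (0.963; *Sox5* at −1.64), −0.07 for 9 bone markers (0.963; *Sp7* at 0.42) and −0.01 for 15 keratinocyte markers (0.680; *Dsp* at −2.20). They were −0.03 for 13 endothelial markers (0.688; *Eng* at −0.88), 0.30 for 16 leukocyte markers (0.531; *Cd14* at −1.97), −0.02 for 12 glial and melanocyte markers (0.827) and 0.12 for 11 adipocyte markers (0.0713; *Cebpa* at 1.84). The leukocyte list was called higher without knockout replicate 3 (0.39, adjusted p = 0.0431) and pointed down without knockout replicate 1 (−0.066, 0.446). The adipocyte list was called higher without wild-type replicate 3 (0.13, 0.0407) or knockout replicate 3 (0.30, 0.0273). *Mitf*, the melanocyte master factor, rose when adjusted over its list alone (1.52 ± 0.28, SE). Median and mean or test differed in sign for the cartilage list, with a mean of −0.26, and for the glial list, with a mean of 0.16. Signalling lists had medians of 0.04 for 22 interferon-response genes (0.932, *Ifih1* at 0.52), 0.22 for 21 inflammatory genes (0.378), 0.07 for 18 unfolded protein stress genes (0.963, *Dnajb9* at −1.77) and −0.13 for 23 TGF-beta and Wnt targets (0.963, *Rspo3* at 2.93), the last with a mean of 0.10. The other probe set of *Rspo3* was at −0.22. *Mmp9*, a matrix protease of the inflammatory list, rose when adjusted over the list alone (2.42 ± 0.46, SE). The median of this list was 0.096 without knockout replicate 1 and 0.44 without wild-type replicate 1, and was not called in either.

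Genes beside the Hoxc cluster, which could carry donor strain sequence around the targeted locus, had a slightly higher median in knockout, but not in replicate 1. By replicate number the medians were −0.10, 0.15 and 0.33. Whether donor sequence plays a part was not tested. Over 115 genes, 100 on one side and 15 up to the chromosome end, the median was 0.12, and 73 lay above 0 (camera adjusted p = 0.019; adjusted p = 0.969 with an estimated correlation). At unadjusted p under 0.05 there were 10, or 8.70% against 6.67% of other genes (Fisher's exact test, two-sided, p = 0.349). The median stood at percentile 90.7 of 15854 windows of 115 neighbouring genes. The call ended without wild-type replicate 2 (0.088) or 3 (0.042) and without knockout replicate 2 (0.13) or 3 (0.072), and the median was 0.20 without wild-type replicate 1 and 0.078 without knockout replicate 1.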

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

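Leaving out both arrays of replicate 1 and the batch term for them were chosen after seeing the data, and the other alternatives before. The count of 0 genes held in 12 of 14 alternatives beside those that leave out 1 array, and moved to 2101 with array weights and to 2542 without replicate 1, where probe sets moved to 1836. Array weights called 0 probe sets (smallest adjusted p 0.0927). Leaving out 1 array gave 0 to 87 genes and 0 to 48 probe sets, and the lone pairs of a genotype were fitted with the spread pooled over both. The replicate block called 0 genes, 0 probe sets and 9 lists against 6, and beyond the calls given with the results it changed no other call. With an estimated correlation 0 lists were called and the medians stayed at 2.05 (Dlk1-Dio3 region), −1.07 (p53 targets), −0.83 (immediate early), −0.56 (hypoxia), 0.56 (cholesterol) and 0.12 (Hoxc neighbours). The matrix list was also called with each array centred on its median (0.23, adjusted p = 0.0321) and without _x_at and _s_at sets (0.24, 0.0488), and the proliferation list without replicate 1 (0.345, 0.00617) and with the batch term (0.48, 1.51e-06). The call of the Hoxc neighbours also ended with 50 genes on each side (0.14, adjusted p = 0.0643). At unadjusted p under 0.05 the block moved 1216 genes to 2017 and 2406 probe sets to 4001. Leaving out 1 array gave medians of 0.082 to 0.34 for matrix genes, −1.77 to −0.70 for p53 targets, −1.21 to −0.67 for immediate early genes, −0.78 to −0.24 for hypoxia genes, 0.24 to 0.98 for cholesterol genes and 0.042 to 0.20 for Hoxc neighbours. The list of all Hox genes was called with array weights (−0.16). The cause was not tested for any change except the fewer arrays. Dim probe sets, such as those of the distal Hoxd genes, lie near the floor, where RMA compresses differences.

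Some differences changed direction, and none of these turned tests passed the threshold before or after. The Polycomb complex 2 median also changed sign without wild-type replicate 1 (−0.27), where its test, pointing down as before, passed (adjusted p = 0.0183). The direction of a list is that of its test, and the values are medians. With the replicate block these were HoxC −0.02, posterior Hox −0.010, maternally expressed imprinted genes 0.027, Polycomb complex 2 0.13 and unfolded protein stress 0.068, and with the batch term the last 4 at −0.010, 0.027, 0.13 and 0.068. Array weights turned posterior Hox (−0.066), the LSD1 complex (−0.20), bone (0.013), endothelial (−0.020) and leukocyte markers (0.041), *Hoxc9* (−0.0078), *Mki67* (−0.45) and *Suz12* (−0.040). Without replicate 1, posterior Hox (−0.045), the LSD1 complex (−0.17), bone (0.022) and leukocyte markers (0.060), *Igf2* (−0.034), *Mki67* (−0.46) and *Suz12* (−0.19) turned. The filter on dim genes turned HoxA (0.18), Polycomb complex 2 (0.21), the LSD1 complex (0.054), leukocyte markers (0.67) and interferon genes (−0.26). The mean of all probe sets turned HoxC (−0.02), cartilage (0.046) and bone (0.024), and leaving out _x_at and _s_at sets turned the LSD1 complex (0.028), unfolded protein stress (0.036), *Dlk1* (−0.01) and *Xist* (0.10). The Y-linked covariate, which differs between genotypes, turned *Acta1* 1.09, *Bcl11b* −0.78, *Btg2* 0.31, *Ccng1* 0.44, *Cdkn1a* 0.42, *Cdkn2a* −0.51, *Eng* 0.10, *Ezh2* −0.83, *Hmgcs1* −0.14, *Hoxc10* 0.37, *Hoxc13* 0.42, *Hoxd11* 0.24, *Hoxd12* 0.20, *Kdm1a* 0.17, *Mest* −0.14, *Mki67* −1.9, *Peg3* 1.51, *Pdgfra* −0.555, *Perp* 1.28, *Phlda3* 0.059, *Ppbp* 0.35, *Sqle* −0.81, *Suz12* −0.78, *Top2a* −1.37, *Tril* −1.29 and *Uty* −1.33. Of these, *Bcl11b*, *Btg2*, *Ccng1*, *Cdkn1a*, *Cdkn2a*, *Hmgcs1*, *Mki67*, *Pdgfra*, *Perp*, *Phlda3*, *Sqle* and *Top2a* were named after their values were seen.

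Over the alternatives that leave out 1 array, ranges that crossed 0 or held a turned test were HoxC −0.12 to 0.19, HoxD −0.10 to 0.057, posterior Hox −0.090 to 0.057, other positional factors −0.016 to 0.17, Polycomb complex 2 −0.27 to 0.37, complex 1 0.044 to 0.19 and the LSD1 complex −0.35 to 0.090. For cell types they were smooth muscle −0.34 to 0.067, skeletal muscle −0.068 to 0.13, cartilage −0.063 to 0.11, bone −0.14 to 0.041, endothelial −0.10 to 0.034, leukocyte −0.066 to 0.46, glial −0.13 to 0.13 and keratinocyte −0.054 to 0.042. Imprinted genes ran from −0.057 to 0.175 (paternally expressed), −0.029 to 0.10 (maternally expressed) and −0.032 to 0.12 (all). Ranges that kept their sign but moved by over 1.5 times were all Hox −0.153 to −0.044, HoxA −0.21 to −0.058, HoxB −0.57 to −0.067, inflammatory 0.096 to 0.44 (smallest adjusted p 0.0552) and adipocyte 0.099 to 0.30. Proliferation ran from −0.52 to 1.23, interferon from −0.22 to 0.46, unfolded protein stress from −0.053 to 0.29 and TGF-beta and Wnt targets from −0.41 to 0.041. Single genes ran from −0.27 to 1.04 (*Ezh2*), −0.18 to 0.22 (*Hoxc10*), −0.85 to 0.82 (*Hoxc8*), −0.12 to 0.23 (*Hoxc9*), −0.14 to 0.078 (*Hoxd11*), −0.10 to 0.037 (*Hoxd12*), −0.043 to 0.29 (*Hoxd13*), −0.34 to 0.89 (*Igf2*), −0.061 to 2.23 (*Lyz2*, named after its values were seen), −1.61 to 1.57 (*Mki67*), −0.60 to 0.43 (*Peg3*), −0.54 to 0.74 (*Suz12*), −0.70 to 1.62 (*Top2a*) and −0.32 to 1.08 (*Uty*).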

Other observations

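The tests of a second p53 list, of the genes flanking the Dlk1-Dio3 region and of other splits of the arrays without a block were set out before their results were seen, and the other tests were chosen after. In replicates 2 and 3 alone, the genes with the largest log2 differences that passed were these. Higher in knockout were *Tmem176a* (5.0), *Iqgap2* (4.98), *Lrrc17* (4.92), *Lrrc15* (4.82), *Tmem176b* (4.63), *Selenop* (4.61), *Crip1* (4.59), *Id4* (4.58), *Osr1* (4.58), *Eif2s3y* (4.52), *Tril* (4.50) and *Thy1* (4.50), a surface protein of fibroblasts. Lower were *Anxa8* (−7.51), *Dynap* (−7.45), *Npr3* (−6.50), *Ppbp* (−5.56), *Ndnf* (−5.53), *Tslp* (−5.28), *Klhl13* (−5.07), *Hapln1* (−5.07), the prostaglandin enzyme *Ptgs2* (−5.01), *Dmrta2* (−4.92), *Smoc2* (−4.83) and *C1qtnf3* (−4.80). In the replicate 1 pair, left out here, most of these genes went the other way. Of the lower genes, these were *Ndnf* (2.81), *Hapln1* (2.35), *Tslp* (2.12), *Smoc2* (0.68), *Ptgs2* (0.29), *Dynap* (0.21), *Ppbp* (0.094) and *C1qtnf3* (0.045). Of the higher genes, they were *Lrrc15* (−1.29), *Id4* (−0.77), *Iqgap2* (−0.61), *Thy1* (−0.44), *Tril* (−0.34) and *Crip1* (−0.087). The others kept their direction at a smaller size, as *Lrrc17* (0.99) and *Npr3* (−0.67). The genes listed are the 12 largest changes in each direction among genes that passed, as the rule for named genes asks, but its use on 2 against 2 arrays was chosen after seeing the data. Leaving out wild-type replicate 2 or 3 as well gave 2740 and 2341 genes, and leaving out knockout replicate 2 or 3 gave 0 and 0, but these fits set 1 array against 2 and take the spread from a single pair, so they do not show which array the calls rest on.

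The replicate 1 arrays of both genotypes stood apart. RNA degradation as the whole cause is argued against by wild-type replicate 1, whose *Gapdh* 3′ minus 5′ difference was −0.18, within the range of the 4 other arrays, although knockout replicate 1 was at 0.75 and its own part stays open. Dilution by cells that lack matrix RNA, as the source of the low proliferation genes, is argued against by the fibroblast matrix list, whose lower median on the 2 arrays was 0.1 (SD of its members 1.01 in wild type and 0.87 in knockout) against −2.0 and −1.38 for proliferation. Admixture of smooth muscle cells or leukocytes stays open by a bar set with the values in view: the lowest of the 4 list medians was 0.19, smooth muscle had 0.83 and 0.41 in wild type and knockout and leukocytes 0.58 in knockout, where *Lyz2*, named after its values were seen, measured 10.57, and the 4 other arrays reached at most −0.00 and −0.14. For a lower share of cycling cells there was no separate test. That 27 of 31 proliferation genes were lower on both arrays than on all 4 others restates the list medians. *Mki67* and *Top2a*, named after their values were seen, were lower in the same way. A lower share of cycling cells and a difference in culture age or processing stay open.

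Targets of p53 were lower in knockout replicates 2 and 3, with *Cdkn1a* at −3.06, *Ccng1* at −3.25, *Mdm2* at −2.97, *Btg2* at −2.95 and *Perp* at −3.25 against wild type of the same replicates, all named after their values were seen, while *Cdkn2a*, which p53 restrains, was at 2.19 and did not pass. RNA degradation is argued against by the higher of the 2 knockout *Gapdh* differences, −0.17, below that of wild-type replicate 3 at −0.03. Lower p53 pathway activity in these cultures is a candidate explanation. A second list of 24 targets that shares no gene with the first had a median of −0.43, with 18 lower. It lay at percentile 0.29 of 10000 random lists matched on mean expression, and its median in the replicate 1 pair was 0.139. The random lists were not matched on correlation between genes, so the percentile may overstate the evidence. An effect of the genotype alike in all 3 pairs cannot be told apart from an effect of single cultures, since the replicate 1 pair, with a median of 0 for the first list, has no second pair like it. Whether loss of *Hotair* or selection in culture lies behind it stays open and untested.

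The RNAs of the Dlk1-Dio3 region were higher in knockout. A change of the wider chromosome region is argued against by the 40 flanking genes, 20 on each side. Their median was −0.17, where a rise of at least 0.3 was needed. The bootstrap interval of −0.41 to −0.085 resampled genes and not arrays, so it leaves out the spread between arrays. It also reached below the band of −0.2 to 0.2 set beforehand for no change. Among the flanking genes *Bcl11b*, named after its values were seen, stood at 2.45. A single deviating probe set is argued against for the region by 18 of 19 probe sets being higher. Of these, however, 11 were of *Meg3*, 4 of *Rian* and 2 of *Mirg*, so they are not independent observations. For *Dlk1* alone it stays open, as 1 of its 2 probe sets was higher and the other was at −0.01. A uniform shortage of fibroblasts in wild type is argued against by the fibroblast matrix list, at a median of 0.24 against 2.05 for the region. The list was mixed, with an SD of 1.26 among its members, 16 above 0 and 8 below. *Dcn* (3.10, though its other probe set was at 0.53) and *Lum* (2.64, named after its values were seen) differed by as much as the region. The list therefore does not settle whether fibroblasts differed between the arrays in another way. An effect of the genotype may remain as a hypothesis, found and tested on the same 6 arrays, and a difference between cultures stays open.

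The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. In 5 of them at least the real 1216 genes had an unadjusted p under 0.05, the highest other count being 2365. The splits that kept the replicate 1 arrays together with wild-type replicate 2, wild-type replicate 3, knockout replicate 2 or knockout replicate 3 gave 2365, 2006, 949 and 2249 genes, so 3 of these 4 exceeded the real split. Among the 4 splits that part all 3 pairs the others gave 137, 45 and 1574. With the replicate block, 2 of these 4 splits gave at least the real 2017, the highest other being 2320, and 4 are too few for a share under 0.05. The same split, with the labels of the replicate 1 pair swapped, gave 35.5% of genes with 1 direction in all 3 pairs against the real 30.5%. All 10 splits gave 0 genes and 0 probe sets past the adjusted threshold, the highest other being 0. At least the real 6 lists were called in 7 splits, the highest other being 11.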
